A study of Mus musculus with 6 samples.

How the data were processed

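RNA sequencing was done on MPC5 cells, a conditionally immortalised mouse podocyte line, kept in high glucose (30 mM) and transfected with small interfering RNA (siRNA). Per the labels' protocols, cells grew at 33 °C with interferon gamma, were held for 7 days at 37 °C without it, and were transfected for 6 h with scrambled or Mettl3-directed siRNA; total RNA was extracted with Trizol and made into Illumina libraries. The 6 libraries were grouped by their titles into 3 control and 3 Mettl3 knockdown libraries, with the replicate numbers 1 to 3 in each group. The series' design text calls the replicates biological. How far the cultures were apart in time is not given in the sources used here.

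The values are gene-level FPKM (fragments scaled by transcript length and by the mapped fragments of the library) as deposited by the authors, per the file headers. The submitters' processing notes name FastQC 0.11.7, cutadapt 1.17, HISAT2 2.0.4, StringTie 1.2.2 and R 2.10.0, with no role or order. They also name the mouse build mm9, but of the 9120 genes in the deposited table, 9112 were matched by identifier to GENCODE M21 and 8379 had exactly its gene span on GRCm38 (mm10), so coordinates are given as GRCm38. How reads were assigned to overlapping genes, to members of gene families or by strand is not given in the sources used here. Every gene in the table has a mean above 0.5 FPKM in at least 1 group (the lowest such mean is 0.501), so genes below that level in both groups are not analysed here. Of the listed genes 8988 are protein-coding.

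The table gives neither counts nor depth. Low values were checked for whole multiples of a single read's worth in 785 genes with a single transcript. In the 150 lowest values per library, at most 21.3% came out whole within a tolerance of 0.05 of a read, where a single trial step gives 10% by chance, so reads were not recovered and the depth behind each value is unknown. FPKM summed to between 173721 and 176526 per library, and between 74 and 118 genes per library were listed at 0. Genes that every cell uses, such as Rps15 and Atp5e, were among those at 0 in 5 of the 6 libraries, so a 0 in this table can be a failed estimate. No value above 0 was shared exactly by any pair of libraries.

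Values were used as deposited, without further scaling. Genes with FPKM of at least 1 in 3 or more of the 6 libraries were kept (8047 genes), and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (moderated statistics with an intensity trend; two-sided). Fold changes are on this log2 scale, knockdown minus control, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Means ± SD are of FPKM. For Mettl3, Timp2 and Igf2bp2 an exact two-sided permutation test on the log2 values was added. With 3 libraries against 3 its smallest possible p is 0.1.

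Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists tested. Camera with an estimated correlation and fry, limma's self-contained test of a common direction, were run beside it. The 24 lists cover m6A machinery, podocyte genes, Notch signalling, TIMPs with matrix metalloproteinases, inflammation, interferon response, apoptosis, p53 targets, extracellular matrix with TGF-beta, actin cytoskeleton, cell cycle, unfolded protein and integrated stress response, antioxidant genes, glycolysis with hypoxia, cholesterol synthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, replication histones, immediate early genes, and markers of endothelial, mesangial or fibroblast, tubule and immune cells. Of their 743 genes, 501 were in the table and 455 were tested. The immune list had 1 of its 19 genes in the table and none past the filter, which left 23 lists. A symbol with more than 1 identifier entered a list by the identifier with the higher mean. Where members are adjusted over the list alone, their p-values are not corrected for the 23 lists, so some passes can arise by chance.

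Genes were named by a rule. It takes Mettl3, Timp2 and Igf2bp2; then, in each direction, the 8 genes with the largest change among those past the threshold with groups that do not overlap and a mean of at least 2 FPKM, filled up where fewer pass by the smallest unadjusted p and said not to pass, with predicted or unnamed models left out; then up to 4 members per list with the smallest unadjusted p. Groups, tests, lists and this rule were set before the data were examined.

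Whether replicate numbers pair the libraries was checked from each library's deviations from its group mean. Libraries of the same number correlated across genes at 0.23, 0.20 and 0.56 (numbers 1, 2 and 3), all above 0.1, so a fit with the replicate number as a block was run. Crossed libraries correlated as well, control 2 with knockdown 1 at 0.26 and control 1 with knockdown 2 at 0.23. The check therefore shows that replicate 3 of both groups goes together, and it does not pair replicates 1 and 2. No label pairs the libraries. The split of replicate 3 follows the bracketed codes in the titles: replicates 1 and 2 of both groups carry codes that begin with HG, and replicate 3 of both groups carries codes of another form. What the codes stand for is not given in the sources used here. Their form was used as a technical split, as a covariate and by restricting the fit to the 4 HG-coded libraries.

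Results were recomputed with pseudocounts of 0.1 and 5, without the filter, with a filter at 5 FPKM, with each library scaled to the same sum, with quantile normalization, with median-of-ratios scaling, with a robust variance without trend, with array weights, with the replicate block, with the code form as a covariate, in the 4 HG-coded libraries, without each library in turn, and, chosen after seeing the data, over genes above 0 in every library whose exons overlap no other annotated gene on the same strand. Fitting and list tests were checked on simulated libraries of the same 8047 genes. With the spread within groups, 42% of genes changed 1.5-fold, 82% of those changed 2-fold, 92% of those changed 3-fold and 94% of those changed 4-fold were recovered, 50 genes at each size, with 2 false calls among 7793 unchanged genes. With the spread within code series and the code covariate, 82%, 84%, 96% and 100% were recovered at these sizes, with 6 false calls among 7794. The list shifted in the simulation was called and 0 others were. Genes were simulated independently of each other and without an offset of replicate 3. The simulation therefore cannot show how often camera calls a list falsely when its genes move together. The changed genes were drawn from the more highly expressed ones, so the shares recovered do not hold for low genes. Genes of all sizes of change and the shifted list were changed in the same simulated libraries, which loosens the adjusted threshold. The shares therefore do not hold where few genes change. Annotation and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.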

Results

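MPC5 cells are conditionally immortalised mouse podocytes, the epithelial cells that cover the outside of the kidney's filtration barrier. Gene expression was measured by RNA sequencing in 6 libraries of these cells in high glucose (30 mM), 3 transfected with scrambled siRNA and 3 with siRNA against Mettl3. The comparison asks which transcripts differ when the cells have less Mettl3 under high glucose, and the series title names the Timp2 transcript as a target of METTL3. Expression is given as FPKM as deposited, for 9120 genes of which 8047 were tested. The sequencing depth behind the values is unknown.

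Mettl3, which encodes the catalytic subunit of the complex that writes N6-methyladenosine (m6A) into mRNA, was lower in each of the 3 knockdown libraries than in any control. Its FPKM was 5.87, 6.34 and 5.75 in control replicates 1 to 3 and 3.68, 3.85 and 3.90 in knockdown replicates 1 to 3, that is 5.99 ± 0.31 (SD, n = 3) against 3.81 ± 0.11 (SD, n = 3), or 36.3% lower. The gene (ENSMUSG00000022160.18, protein-coding) lies on the minus strand of chromosome 14 from 52294841 to 52305128, and the value covers the whole gene; the position of the siRNA target is not given in the sources used here. The log2 fold change was -0.54 (SE 0.10, limma), with an adjusted p of 0.80 over all genes and of 0.0174 adjusted over the list alone among the 20 tested m6A genes. The exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. Among the other m6A genes the smallest unadjusted p-values belonged to the eraser Alkbh5 (15.6 ± 1.1 against 17.6 ± 0.68 FPKM, SD), to Rbm15b (11.1 ± 2.0 against 9.0 ± 1.9) and to Cbll1 (1.68 ± 0.21 against 1.31 ± 0.31). None of them passed, except Rbm15b with the code covariate when adjusted over the list alone (limma adjusted p = 0.0474). The m6A list had 12 members above 0 and 8 below, with a median log2 fold change of 0.02 (camera adjusted p = 0.69).

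**Figure D1:**
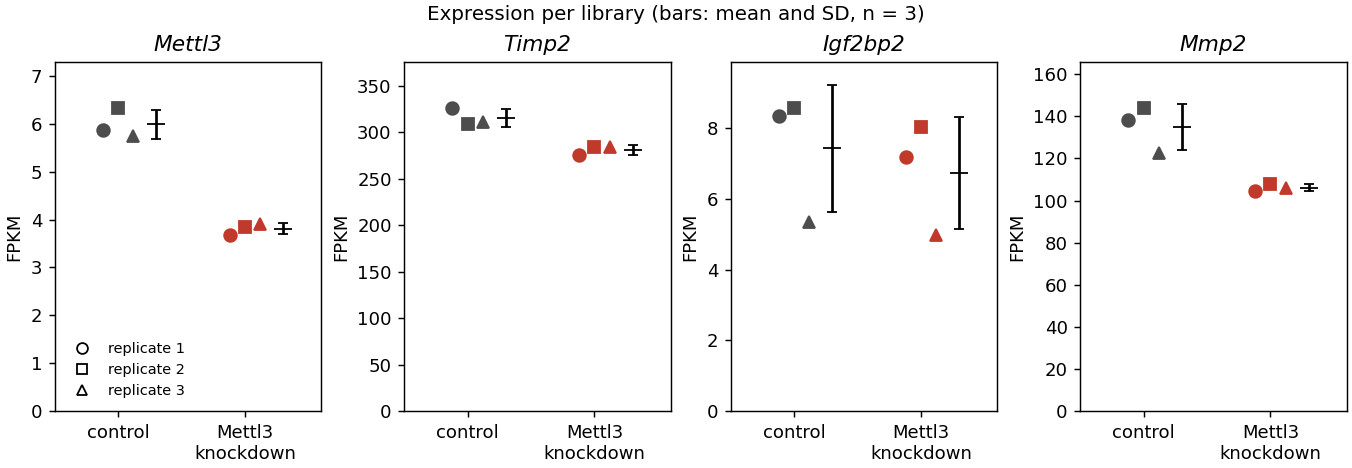
FPKM (vertical axes, from 0) of Mettl3, Timp2, Igf2bp2 and Mmp2 in each of the 6 libraries, with symbols for replicate numbers and bars for the mean and SD of 3 libraries. The 3 knockdown libraries sit below all controls for Mettl3 (3.68 to 3.90 against 5.75 to 6.34), Timp2 and Mmp2, while for Igf2bp2 the groups overlap.

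Timp2, which encodes an inhibitor of matrix metalloproteinases, was an abundant transcript and was also lower in each knockdown library than in any control. It measured 327, 309 and 312 FPKM in control replicates 1 to 3 and 275, 284 and 285 in knockdown replicates 1 to 3, a mean of 316 ± 9.6 (SD, n = 3) against 282 ± 5.3 (SD, n = 3), or 10.9% lower. The gene (ENSMUSG00000017466.9, protein-coding) spans 118301069 to 118355740 on the minus strand of chromosome 11. Its log2 fold change was -0.16 (SE 0.07, limma). This passed neither the threshold over all genes (adjusted p = 0.998) nor that adjusted over the list alone (0.188), and the exact permutation p was 0.1, again the smallest possible. Adjusted over the list alone, Timp2 passed with the code covariate (limma adjusted p = 0.0299) and not with the replicate block (0.0653). Igf2bp2, an m6A reader (ENSMUSG00000033581.16, chromosome 16, 22059009 to 22163299, minus strand), measured 7.43 ± 1.8 against 6.72 ± 1.6 FPKM, with overlapping groups, a log2 fold change of -0.12 (SE 0.22) and an exact permutation p of 0.5.

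Within the list of TIMPs and metalloproteinases, Mmp2 (gelatinase A, whose activation on the cell surface involves TIMP2) was the 1 gene of 8 that passed when adjusted over the list alone (limma adjusted p = 0.0381). Mmp2 (ENSMUSG00000031740.8, chromosome 8, 92827291 to 92853420, plus strand) measured 135 ± 11 FPKM in controls and 106 ± 1.5 in knockdown (SD, n = 3 each), a log2 fold change of -0.34 (SE 0.08); over all genes its limma adjusted p was 0.998. Timp1 was listed at 12.4, 12.8 and 14.7 FPKM in controls and at 12.4, 0 and 16.0 in knockdown replicates 1 to 3. Mmp19 was listed at 0 in control replicates 1 and 3 and in knockdown replicate 3, and at 2.48 to 3.44 elsewhere. The list as a whole was not called (4 members above 0 and 4 below, camera adjusted p = 0.29).

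The largest differences among the libraries did not follow the knockdown. Replicate 3 of both groups stood apart from the other 4 libraries on the first principal component, which held 44.3% of the variance, and the titles give these libraries codes of another form than the rest. With the knockdown accounted for, limma called 1513 of the 8047 genes different between replicate 3 and the others, 501 higher and 1012 lower in replicate 3. Since replicate 3 is present once in each group, fold changes between the groups are the same with and without a term for it, and a term for the code form lowers their error in 7800 of the 8047 genes.

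**Figure D2:**
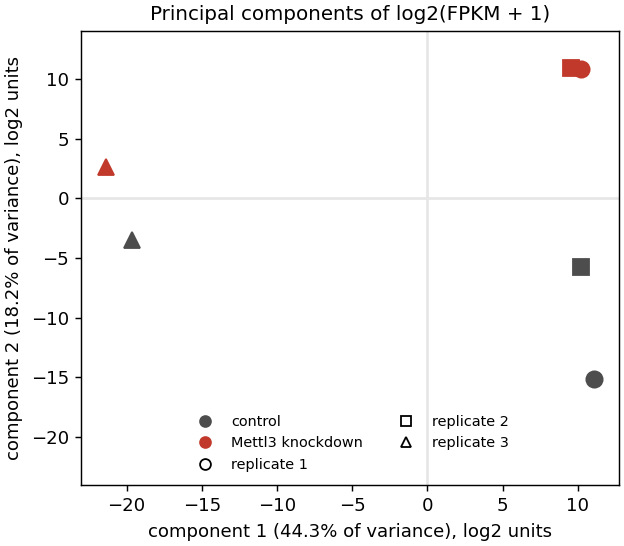
First and second principal components of log2(FPKM + 1) over the 8047 tested genes, in log2 units, for the 6 libraries (colour, group; symbol, replicate number). The first component (44.3% of variance) parts replicate 3 of both groups from the other 4 libraries, and on the second (18.2%) each knockdown library lies above the control libraries.

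No gene passed the threshold between knockdown and control. By limma, 0 of 8047 genes had an adjusted p under 0.05 (smallest, 0.134) and 366 had an unadjusted p under 0.05, against 402 by chance. The groups did not overlap in 811 genes (10.1%, where chance gives 10% for 3 against 3), 488 of them higher and 323 lower in knockdown. Both chance figures ignore the offset of replicate 3, which widens the spread within each group. A count near chance here therefore does not show that no gene changed. With the replicate number as a block the count past the threshold was again 0 (smallest limma adjusted p, 0.210). There 872 genes had an unadjusted p under 0.05, against 402 by chance. With the code form as a covariate it was also 0 (smallest limma adjusted p, 0.0726, with 12 genes under 0.1), with 970 genes at an unadjusted p under 0.05. Genes that move together can raise such counts, so the excess is not a test. Within the 4 HG-coded libraries 2 genes passed, the actin-binding protein gene Tagln2 and the lipid droplet gene Plin2, both higher in knockdown. Tagln2 measured 148 and 141 FPKM in control replicates 1 and 2 and 266 and 264 in knockdown replicates 1 and 2, but 209 in control and 197 in knockdown replicate 3; Plin2 was listed at 0 in both of those controls and at 8.89 and 10.7 in knockdown replicates 1 and 2, but at 6.48 in control and 0 in knockdown replicate 3. Replicate 3 holds 1 library per group, so no test within it was made. The count was 2 without control replicate 2, both of them overlapping models named Raver1, and 2 without knockdown replicate 3, namely Shisa5 and Lars2. Shisa5 and Lars2 were above all controls in the replicate left out (Lars2 at 26.6 FPKM there, at 1.2 and 2.6 in knockdown replicates 1 and 2 and at 16.7 to 19.6 in controls). These 6 gene models fell outside the naming rule, apart from Tagln2 and 1 of the Raver1 models, and were chosen after their values were seen.

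Of the genes with the smallest unadjusted p among those higher in knockdown, none passed. The co-chaperone gene Dnajb1 (chromosome 8, 83608193 to 83612653) measured 8.27 ± 1.6 FPKM in controls and 16.1 ± 0.85 in knockdown (SD, n = 3; log2 fold change 0.90, SE 0.14, limma adjusted p = 0.80), and Xbp1, a transcription factor of the unfolded protein response, measured 31.4 ± 3.3 against 44.5 ± 3.3 (log2 fold change 0.49, SE 0.10). The others were the membrane fusion gene Snap23 (10.3 ± 1.2 against 17.0 ± 1.5 FPKM), the small GTPase gene Arf1 (492 ± 12 against 629 ± 22), Prdm6 (8.97 ± 0.42 against 13.4 ± 1.1), Syde1 (5.76 ± 0.60 against 10.6 ± 2.0), Plekha2 (2.45 ± 0.07 against 4.46 ± 0.85) and Lmbrd1, a lysosomal cobalamin transport gene listed at 0.02 to 0.07 FPKM in controls and at 1.45 to 1.96 in knockdown. Lmbrd1 passed with a robust variance without trend (adjusted p = 0.0437). With the code covariate none of these genes passed, and their limma adjusted p ranged from 0.0726 (Lmbrd1 and Xbp1) to 0.147 (Syde1). Among genes lower in knockdown, none past the threshold either, Plekha3 measured 28.5 ± 0.44 FPKM against 19.4 ± 2.2 (log2 fold change -0.54, SE 0.10), the actin capping gene Capza1 44.7 ± 1.4 against 33.7 ± 2.2, the transcriptional repressor gene Bhlhe40 24.3 ± 1.9 against 17.6 ± 0.26, Tmtc3 5.15 ± 0.70 against 2.78 ± 0.26 and Rasd1 3.29 ± 1.1 against 0.90 ± 0.33. Mettl3 itself and Raver1 were also among these; 7 of the 8 genes lower in knockdown are given here. The Raver1 model in question (ENSMUSG00000111497.1, 17.96 ± 6.8 against 5.89 ± 0.55 FPKM) shares exons on the same strand with a second model of that name (ENSMUSG00000010205.11), which was listed at 0 in control replicates 1 and 3 and at 23.5 to 25.5 FPKM in the other 4 libraries, so the reads of both are uncertain.

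As groups, genes of cell division were lower in knockdown. All 23 tested replication histone genes and all 30 tested cell cycle genes had a log2 fold change below 0, with medians of -0.44 and -0.32. Without a term for replicate 3, members of each list moved together (correlation estimated by camera, 0.77 for histones and 0.87 for cell cycle). With the code covariate the estimates were 0.14 and 0.03, so most of this shared movement followed replicate 3. The counts are still not taken as independent observations. By limma 8 of the 23 histone genes and 0 of the 30 cell cycle genes had an unadjusted p under 0.05. Among histones, Hist1h2bj (chromosome 13, 22043214 to 22043676) measured 21.6 ± 3.2 against 13.2 ± 2.6 FPKM (SD, n = 3 each), Hist1h3e 16.0 ± 2.1 against 10.6 ± 1.5, Hist1h3b 109 ± 13 against 74.2 ± 18 and Hist1h2bk 36.0 ± 5.3 against 27.5 ± 3.1. Histone genes are near-identical copies, so the level of any single one is uncertain. Among cell cycle genes, the replication licensing gene Mcm6 measured 4.86 ± 2.1 against 2.70 ± 1.2 FPKM, and the cyclin genes Ccne2 and Ccnb2 6.39 ± 2.3 against 4.19 ± 0.90 and 6.45 ± 2.1 against 4.13 ± 2.5. The mitotic kinase gene Plk1 measured 13.6 ± 4.5 against 10.1 ± 5.0.

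Camera with the preset correlation called both lists (adjusted p = 2.24e-13 for histones and 1.26e-04 for cell cycle). With an estimated correlation neither call held (adjusted p = 0.668 for histones and 0.761 for cell cycle), and fry called neither (0.673 and 0.891). With the code covariate fry called the cell cycle list (adjusted p = 0.0316) and not the histone list (0.0523), and with the replicate block it called neither (0.236 and 0.255). Its test for change in either direction was not specific to these lists: with the block it called 9 of 23, namely Notch (adjusted p = 0.00423, the smallest), the unfolded protein and integrated stress list (0.0138), histones (0.0168), cell cycle, m6A and podocyte genes (0.0238 each), and inflammation, antioxidant and p53 genes (0.0292 each). Without the block it called 0. Camera with an estimated correlation called neither list with the block (0.414 for both) or the covariate (0.166 and 0.145). No member passed over all genes or when adjusted over the list alone; with the replicate block, 17 histone and 13 cell cycle genes passed adjusted over the list alone, and 17 and 16 did so with the code covariate. Both lists were also lower in replicate 3 of both groups, with medians of -0.48 and -0.93 against the other 4 libraries. Within the 4 HG-coded libraries the medians of knockdown against control were -0.41 (22 of 23 histone genes below 0) and -0.30 (29 of 30 cell cycle genes), and within the replicate 3 pair they were -0.47 (22 of 23) and -0.21 (26 of 30). The histone list was called without any single library. The cell cycle list was not called without control replicate 1 (median -0.16, adjusted p = 0.0738), control replicate 2 (-0.14, 0.0945) or knockdown replicate 3 (-0.02, 0.526). Without control replicate 3 its median was -0.62, and without knockdown replicate 3 the histone median was -0.25. Leaving out any 1 library changes the weight of replicate 3 in its group, and these fits had no term for replicate 3. The medians without a library therefore carry part of the replicate 3 offset (-0.93 for cell cycle and -0.48 for histones).

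**Figure D3:**
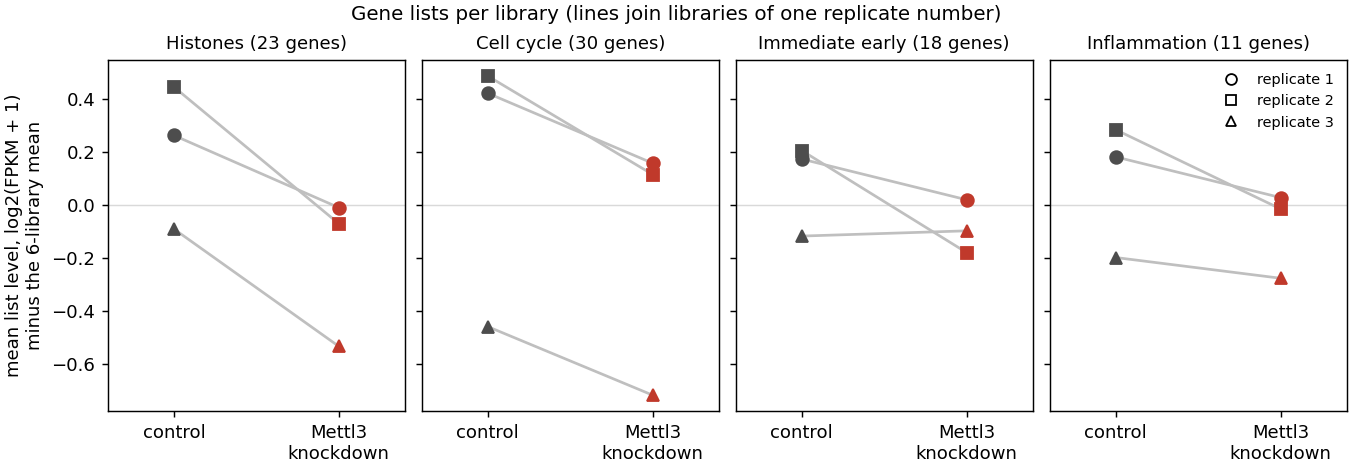
Mean level of the histone, cell cycle, immediate early and inflammation lists in each library, as log2(FPKM + 1) minus each gene's mean over the 6 libraries; symbols are replicate numbers and lines join libraries of the same number. The histone and cell cycle lists are lower in the knockdown library of every number and also lower in replicate 3 (cell cycle at -0.46 in control and -0.72 in knockdown replicate 3).

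Immediate early genes, which respond quickly to growth factors and stress, were also lower as a group: 13 of 18 were below 0, with a median of -0.21 (camera adjusted p = 1.98e-04; adjusted p = 0.493 with an estimated correlation). The transcription factor genes Egr1 and Fosl1 measured 10.6 ± 3.5 against 6.42 ± 1.6 FPKM and 9.02 ± 2.1 against 6.23 ± 0.82, the phosphatase gene Dusp5 1.71 ± 0.08 against 1.01 ± 0.22 and Ier2 7.79 ± 1.1 against 6.23 ± 0.26. None passed alone, except Egr1 when adjusted over the list alone with the replicate block (limma adjusted p = 0.0184) or the code covariate (0.00626). Of the inflammation genes 8 of 11 were below 0, with a median of -0.14 (camera adjusted p = 0.0236; adjusted p = 0.668 with an estimated correlation). Nfkbia, which encodes the NF-kappaB inhibitor and is itself induced by NF-kappaB, measured 30.9 ± 4.7 against 21.6 ± 2.1 FPKM (SD, n = 3 each), Relb 4.76 ± 0.32 against 3.70 ± 0.29 and Ptgs2 4.13 ± 2.4 against 2.32 ± 0.60, while Rela measured 10.9 ± 1.8 against 12.4 ± 1.1. The inflammation list was not called with a filter at 5 FPKM (adjusted p = 0.311), without control replicate 1 (0.0738), without control replicate 2 (0.25) or without knockdown replicate 3 (0.213). In the replicate 3 pair alone the medians were -0.07 for immediate early and -0.03 for inflammation genes, and the mean level of the immediate early list was slightly higher in knockdown (-0.098 against -0.118 in control). Of the 8 interferon genes 7 were below 0, with a median of -0.17, and the list was not called (camera adjusted p = 0.107) except with the replicate block (0.0177), the code covariate (0.0234), array weights (0.0386), within the HG-coded libraries (0.00857), without control replicate 3 (8.44e-04) and without knockdown replicate 2 (0.00881). With an estimated correlation none of these calls held (adjusted p of 0.606 to 0.808). The interferon genes were lower in replicate 3 (median -0.53 against the other 4 libraries), and leaving out a library unbalances it. Without each library in turn, the median of the interferon list ranged from -0.40 (without control replicate 3) to -0.06 (without control replicate 2, 5 of 8 genes below 0). Its members with the smallest unadjusted p were Irf1 (3.01 ± 0.92 against 2.00 ± 0.50 FPKM), Stat2, H2-D1 and Tap1.

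Genes of the podocyte itself were not shifted together. Of the 14 podocyte genes tested (35 were on the list), 10 were above 0 and 4 below, with a median of 0.03 (camera adjusted p = 0.81). Vegfa, the endothelial growth factor that podocytes secrete, measured 63.7 ± 3.4 FPKM in controls and 49.5 ± 2.2 in knockdown (SD, n = 3 each). It was the 1 podocyte gene that passed adjusted over the list alone (limma adjusted p = 0.0426). Adjusted over the glycolysis list, which also holds it, Vegfa did not pass (0.0912), and its limma adjusted p over all genes was 0.87. Dach1 measured 3.10 ± 0.44 against 4.72 ± 1.3 FPKM, the tight junction gene Tjp1 46.6 ± 2.0 against 50.5 ± 4.5 and Magi2 2.54 ± 0.33 against 2.18 ± 0.39. In the Notch list, 14 members were above 0 and 10 below (median 0.03, camera adjusted p = 0.70). The smallest unadjusted p there was that of Rbpj, the DNA-binding factor through which Notch acts, at 10.8 ± 0.81 against 6.95 ± 1.5 FPKM (limma adjusted p = 0.127, adjusted over the list alone). Dtx3 and Notch2, below 0, and Jag1, above 0, followed.

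Matrix and cytoskeletal lists were not called. In the list of extracellular matrix and TGF-beta genes 13 of 30 members were above 0 (median -0.02, camera adjusted p = 0.81); Tgfb2 measured 1.94 ± 0.20 against 3.19 ± 0.36 FPKM, Tgfb1 29.4 ± 2.3 against 25.01 ± 0.82, the collagen crosslinking gene Lox 49.5 ± 21 against 76.8 ± 17 and Tnc 49.6 ± 1.1 against 44.9 ± 3.6. Of 35 actin cytoskeleton genes 22 were above 0 (median 0.04, adjusted p = 0.42). Tpm1 measured 55.9 ± 1.2 against 67.8 ± 2.3 FPKM, Tagln2 166 ± 37 against 242 ± 39, Tpm3 36.7 ± 2.4 against 42.3 ± 3.0 and Actb 1673 ± 195 against 1363 ± 231.

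Stress and metabolic lists were not called either. In the unfolded protein and integrated stress list 22 of 31 members were below 0 (median -0.04, camera adjusted p = 0.29), with Xbp1 above 0 and the other 3 named members, Ern1, Sel1l and Shmt2, below. This list (adjusted p = 0.0164) and the cholesterol synthesis list (0.0152) were called, both lower, without knockdown replicate 3, and with an estimated correlation neither call held (adjusted p = 0.754 for both). That setting leaves replicate 3 among the controls alone. Both lists were higher in replicate 3 (medians of 0.20 and 0.41 against the other 4 libraries), so these calls carry its offset. Within the 4 HG-coded libraries neither was called (medians of -0.05 and -0.02, camera adjusted p = 0.166 and 0.627). With all libraries cholesterol synthesis had 14 of 25 members below 0 (median -0.03, adjusted p = 0.70). Its median ranged from -0.20 without knockdown replicate 3 to 0.10 without control replicate 3, where 7 of 25 were below 0 and the list was not called. Of its named members Insig1 and Cyp51 were below 0 and Dhcr7 was above. Sqle was listed at 0.04 FPKM in control replicate 2 and at 11.6 to 19.1 elsewhere. Antioxidant genes had 13 of 22 below 0 (median -0.02, adjusted p = 0.40), among them the ferritin gene Ftl1 (766 ± 86 against 637 ± 69 FPKM), Gclm and Cat, with Txnip, a gene induced by glucose, at 38.5 ± 8.9 against 51.6 ± 10.3. Glycolysis and hypoxia genes had 17 of 30 below 0 (median -0.02, adjusted p = 0.42), with Vegfa and Pfkfb4 below 0 and P4ha1 and Pfkm above. Nuclear oxidative phosphorylation genes had 26 of 37 above 0 (median 0.06, adjusted p = 0.42), among them Ndufv1 (15.3 ± 1.5 against 18.8 ± 0.68 FPKM), Uqcrfs1 and Ndufa8, with Cox7a2 below 0. Ribosomal protein genes split 27 above and 29 below (median 0.00, adjusted p = 0.77), with Rpl6, Rpl13 and Rps9 above 0 and Rpl19 below.

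The p53 target list had 9 members above 0 and 10 below (median -0.02, camera adjusted p = 0.81), with the cyclin gene Ccnd1 at 31.2 ± 6.6 against 22.7 ± 3.2 FPKM and Zmat3, Plk2 and Xpc above 0. Apoptosis genes had 8 of 12 below 0 (median -0.03, adjusted p = 0.42), with Mcl1, Bak1 and Bcl2l11 below 0 and Bad above. Lists of markers of other kidney cells were not called. Tested were 9 of 18 mesangial or fibroblast markers, 2 of 18 endothelial markers and 1 of 19 tubule markers, against 14 of 35 podocyte genes. Of 9 mesangial or fibroblast markers 6 were above 0 (median 0.15, adjusted p = 0.77; Des and Cspg4 above, Fbln1 and Pdgfra below), of 2 endothelial markers Eng was above and Ehd3 below (adjusted p = 0.82), and the 1 tubule marker, Krt8, measured 1.33 ± 0.08 against 1.10 ± 0.10 FPKM (adjusted p = 0.42). Of 13 mitochondrially encoded genes 4 were in the table and 1 was tested. This gene, mt-Co3, measured 1.35 ± 0.49 against 0.90 ± 0.56 FPKM (camera adjusted p = 0.42), close to the filter of 1 FPKM. The median and the mean of members had opposite signs in the lists of TIMPs, m6A machinery, Notch, cholesterol synthesis, ribosomal proteins, extracellular matrix and p53 targets. Other genes named above also passed adjusted over the list alone with a term in the fit. With both the replicate block and the code covariate these were Nfkbia, Ftl1, Txnip, Lox, Ccnd1 and Xbp1; with the covariate and not the block they were Tpm1, Mcl1, Tgfb2, Irf1 and, in the glycolysis list, Vegfa. Rbpj passed with the block and not the covariate.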

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

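The setting restricted to genes above 0 in every library without same-strand exon overlaps was chosen after seeing the data. Mettl3 and Timp2 kept their direction and stayed short of the threshold in all 19 alternatives, with log2 fold changes of -0.64 to -0.32 and -0.19 to -0.10 and adjusted p-values of 0.112 to 1.00 and 0.237 to 1.00. The count of genes past the threshold, 0, became 1 with a robust variance without trend and 2 in the 4 HG-coded libraries, and ranged from 0 to 2 without each library in turn; the other settings gave 0. Lmbrd1, Plin2, Shisa5 and 1 Raver1 model among them were listed near 0 in some libraries; the cause was not tested. The count of 4 lists became 0 with camera's estimated correlation and 0 with fry, ranged from 2 to 5 without each library, and was 3 to 5 elsewhere. With the estimated correlation or fry the medians are those of the main test by construction (-0.32 cell cycle, -0.44 histones, -0.21 immediate early, -0.14 inflammation) and no call held. The inflammation call also ended with a filter at 5 FPKM (median -0.14), with fewer genes tested. Without each library, medians ranged from -0.211 to -0.0925 for inflammation, where the cause was not tested, and from -0.623 to -0.0230 for cell cycle. Both cell cycle extremes leave out 1 replicate 3 library, where this list is lower (median -0.93), which unbalances the groups. Leaving out any other library also changes the weight of replicate 3 in its group, to a lesser degree. The replicate block left the counts at 0 genes and 5 lists (interferon added) and changed no other list call of camera. Over 1780 values of 96 other named genes, 1774 kept direction and side, 3 passed the threshold and 3 reversed, none past it: Sqle without control replicate 2 (-0.182; range without each library up to 1.95), Timp1 without knockdown replicate 2 (0.0834; range down to -1.96) and Igf2bp2 without knockdown replicate 3 (0.0523; range down to -0.314). The fit for counts was not run, since the values are FPKM. Without counts, the part of the spread that comes from depth is unknown.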

Other observations

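The tests of technical explanations for the lower histone and cell cycle lists were chosen only after the result was seen; the tests of the replicate 3 libraries and of the genes listed at 0 were set before their results were seen. The replicate 3 genes named here were chosen after their values were seen.

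Replicate 3 of both groups differed from the other 4 libraries in matrix, division, lipid and interferon genes. The collagen genes Col12a1 and Col3a1 were higher. Col12a1 had a mean of 153 FPKM in the replicate 3 pair against 45.2 in the other 4 libraries (log2 difference 1.74, SE 0.05, limma adjusted p = 1.08e-04 with the knockdown accounted for), Col3a1 734 against 317, and the smooth muscle actin gene Acta2 57.8 against 16.0. Of 30 extracellular matrix and TGF-beta genes 20 passed, 15 of them higher. Igfbp5, a binding protein of insulin-like growth factors, was at 48.9 against 9.45 FPKM. Cell cycle genes were lower, 26 of 30 past the threshold and all 26 lower, among them Top2a (7.23 against 17.7 FPKM), Rrm2 (7.60 against 18.7) and Mcm5 (3.84 against 9.83).

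In the same contrast 15 of 25 cholesterol synthesis genes passed, all 15 higher, such as Acly (225 against 141 FPKM) and Idi1 (11.1 against 7.38), and 6 of 8 interferon genes passed, all lower. Sod2 and Socs3, which cytokine signalling induces, were at 11.5 against 29.3 and 3.69 against 16.6 FPKM. Atf4, a factor of the integrated stress response, was at 233 against 127. Camera with the preset correlation called the cell cycle, cholesterol, histone, matrix, p53, interferon, stress response, ribosomal protein and actin lists (adjusted p from 4.91e-15 to 0.0335); with an estimated correlation none was called (smallest adjusted p, 0.146 for cell cycle). Each side of this contrast holds control and knockdown libraries.

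Technical readings of the replicate 3 difference were tested. A bias by gene length would tie the difference to exonic length, but across 8042 genes, which are not independent replicates, Spearman's rho was -0.0707. A difference in scaling would be removed by quantile normalization, which left 1370 genes past the threshold against 1513 without it (90.5%). A difference of batch, passage, culture day or confluence stays open: the titles give these libraries another form of code and no label says what it marks. No biological explanation was tested.

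The lower histone and cell cycle lists in knockdown are a pattern of lists, and no gene passed over all genes. Without a term for replicate 3 their members moved together, while with the code covariate the estimated correlations were 0.14 and 0.03. Replication histone mRNAs lack a poly(A) tail, so a difference in capture would bear on the histone list alone. There (median -0.44) it cannot be told apart from a change in the share of cells in S phase. That median lies below the cell cycle median of -0.32 and above the lowest cell cycle gene (-0.65). The position decides nothing, since a capture difference can have any size. An offset between the code series is balanced between the groups, and the pattern did not rest on the replicate 3 pair alone, since within the 4 HG-coded libraries the median nearer 0 of both lists was still -0.30. Differences in growth between dishes stay open: the cell cycle level ranged within a group by up to 3.17 times its difference between groups, which is the gap of replicate 3, while it was lower in knockdown in each same-numbered pair (by 0.26, 0.37 and 0.26) and ranged by 0.07 and 0.04 within the HG-coded controls and knockdowns, with 2 dishes in each. Slower division after Mettl3 knockdown stays open too and was not tested.

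The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest of the other splits 6. As large a count as the real one came from all 10, which is certain for a count of 0 and decides nothing. For lists the real split gave 4 and the highest other 11, and 5 of the 10 splits gave as many. The 4 splits that put both replicate 3 libraries on one side gave 5 to 11 lists and 937 to 1016 genes at an unadjusted p under 0.05, which points to the structure of the samples described above; the fit with the replicate block, which removes it, gave 0 genes and 5 lists. Like the real split, 3 others part every same-numbered pair; they gave 0 to 1 lists, up to 3 genes past the threshold and at most 143 genes at an unadjusted p under 0.05, where the real one gave 366.

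In 39 genes the table lists 0 FPKM in at least 1 library and 5 FPKM or more in another, with no relation to the groups required. Atp5e (25.8 FPKM), Ndufa1 (23.5), Fam162a (16.0) and Rps15 (7.67) were above 0 in control replicate 3 alone, Timp1 was at 0 in knockdown replicate 2 alone, and Gapdh, a glycolytic enzyme usually among the most abundant transcripts, was listed at 1.10 to 1.80 FPKM. Exons of another gene on the same strand overlapped 28.9% of these genes against 9.50% of the others (Fisher's exact test, two-sided p = 6.24e-04), and their median exonic length was 1082 bases against 4716 (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Reads shared between overlapping models and short transcripts are therefore both candidate explanations, and how the authors' software treated them is not given in the sources used here. Timp1, Plin2 and 1 Raver1 model, named among the results above, also belong to this set. Timp1 has 888 exonic bases and the Raver1 model overlaps other genes. Plin2 has no such overlap and 3512 exonic bases, so neither candidate is evident for it.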
